A study of Caenorhabditis elegans with 42 samples.

How the data were processed

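The series covers 42 libraries of Caenorhabditis elegans, 30 of embryos or L4 larvae and 12 of RNA pulled down through FLAG-tagged ADR-1 or of its input in young adults. Per the labels, embryos were released from adults with hypochlorite, and L4 larvae were grown from synchronised hatchlings. Libraries came from the high molecular weight RNA fraction after removal of ribosomal RNA, with a stranded kit. The submitters' processing notes name Bowtie, DESeq and the genome build ce10, with no version and no role.

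For each mutant strain and stage the authors deposited 1 table with a line per annotated transcript. Its expression signal, per the file headers, is the authors' normalised mean count over the libraries of a strain, scaled anew in each table, so that the N2 level of a gene differs between tables. The fold change in the deposited tables is the authors' ratio of the mutant mean to the N2 mean, and is undefined or infinite where a mean is 0. The p-value and its adjusted value are the authors' own, as deposited, and the adjusted p was recomputed by the Benjamini-Hochberg method from the deposited p within 0.01 for every transcript that has one. For the pulled-down RNA the authors deposited a log2 fold change of each tagged strain over the negative control. It comes with a standard error and a test statistic, which are score columns of the deposited tables. How input libraries entered that comparison is not given in the sources used here. These tables hold bound genes alone. The authors also deposited lists of gene names for each class of change, whose rule is not given in the sources used here. The tables spell the strain RB886 as RB668, and the strain name of the labels is used.

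The deposited values are group means, so no value per library entered any test, and no library could be left out, no replicate block added and no count model fitted. The spacing of the rounded means of low genes is a whole number of reads divided by library factors. From it the number of libraries behind each mean could be counted, and it was that of the labels except in BB2 embryos, where the spacing gave 3 libraries and the labels give 2. These factors lay between 0.663 and 1.30, a range that limits how far libraries of one strain differed in depth. Depth per library is otherwise unknown.

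Each gene was represented by the transcript with the largest sum of means. A gene was called higher or lower at a deposited adjusted p under 0.05, the design fixed for tables that hold only the authors' comparisons. That p was compared with counting error, computed from the means and their numbers of libraries. Genes with the same means as another gene, 2707 in 695 sets, share reads with copies, and 804 tRNA genes were recognised by name. Genes listed at 0 in every mean numbered 1152. Overlaps of calls are given with the number that independent lists would share, per direction. Unchanged strains were simulated 100 times against shared N2 libraries with counting error, with a spread of 20% between libraries and with the largest spread that the alleles allow, taking the smaller value of adr-1 and adr-2 at each stage. That limit comes from the mutant libraries alone and was used for N2 too. Libraries were drawn independently, although dates in the titles are shared by some libraries of different strains and by a pair of RB886 embryo libraries. A call in both simulated strains had to be in the same direction. A further pair of unchanged strains was drawn against the same N2 libraries, after the data were seen, to give the number of calls in all 4. A mutant mean listed at 0 counted as lower where the authors' adjusted p passed.

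Before the data were examined, 18 gene lists were fixed: editing enzymes, transcripts with long-known editing sites, RNA interference, intracellular pathogen response, antimicrobial response, vitellogenins, sperm, oocyte and germline, early zygotic genes, cuticle collagens, moulting, vulval development, neurons, muscle, intestine, stress, histones and cytosolic ribosomal proteins. Of 1041 names 1033 were found, some through the names that the WBcel235 annotation pairs with sequence names. That annotation differs from the authors' build and was used for names and neighbours only. For each list the median log2 ratio of the means, each with a pseudocount of 1, was compared with 10000 random lists of the same size matched in 20 bins of expression. The permutation p is two-sided, 0.0001 is the smallest it can give, and it was adjusted over 144 tests. The authors' lists (48 tests) and the bound genes (16 tests) were treated likewise, the latter also with a two-sided Fisher's exact test across genes. The number of bound genes in each of the 18 lists was compared with random lists matched on the average of all deposited means, a test added after the data were seen and adjusted over 18. Genes are not independent replicates, so these p-values describe these tables.

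The genes named were chosen by a rule fixed before the data were examined: adr-1 and adr-2 in every comparison; for each gene and stage, 10 genes higher and 10 lower with the largest smaller change of the alleles, called in both at a mean of at least 10; 3 higher and 3 lower per single strain; up to 4 members per list with the smallest adjusted p; and 10 bound genes with the largest smaller enrichment. Bound genes treated as having no finite fold in either tagged strain were left out of that ranking. Not every gene so chosen is printed, and genes changed in all 4 strains, genes that mark both adr-2 strains, and some values of chosen genes in further comparisons were singled out after their values were seen. The alternatives were stricter thresholds, a fold limit, filters on low values, recentred fold changes, unmatched random lists and means in place of medians, with others added later. The counting test recovered 90.0% and 99.0% of genes changed 2-fold and 4-fold in data simulated on the 15174 genes of BB19 embryos, and 89.0% and 99.0% on the 16337 genes of the libraries labelled BB2 at L4. The list test was tried on independent random values for the same genes, where it called 6.50% and 2.50% of 200 unchanged lists. Lists of genes that vary together or share reads were not tried. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.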

Results

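Caenorhabditis elegans carries a pair of genes of the ADAR family, which act on adenosines in double-stranded RNA. ADR-2 is the deaminase that turns adenosine into inosine, and ADR-1 is a double-stranded RNA-binding relative that regulates where ADR-2 edits. The series set animals in which editing is altered (adr-1 mutants) beside animals with no editing (adr-2 mutants) during development. RNA was sequenced from embryos and from L4 larvae, the last larval stage, of the wildtype N2 and of 4 mutant strains. BB19 carries the adr-1 allele tm668, BB2 the adr-1 allele gv6, RB886 the adr-2 allele ok735 and BB3 the adr-2 allele gv42. The labels give 4 N2, 3 BB19, 2 BB2, 3 RB886 and 3 BB3 libraries of embryos and 3 libraries of each strain at L4. Young adults of 3 further strains gave 12 libraries of RNA pulled down with an anti-FLAG antibody and of its input, 2 of each kind per strain. HH76 and HH134 make FLAG-tagged ADR-1, the first with and the second without adr-2, and BB21 is the negative control without the tag. The library titles and the authors' lists name this control adr-1, so it may lack adr-1 as well as the tag.

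The values are group means of normalised read counts for 34873 transcripts of 30304 genes, with a fold change and an adjusted p for each of the 8 comparisons of a mutant strain with N2. The means of one strain summed to between 14175075.5 and 17398074.9 normalised reads. No value per library was used, so no value below has an SD, and the 2 alleles of each gene served as the repeat of its genotype. Other differences that 2 strains may share were not tested, so agreement of alleles need not come from the mutated gene. The labels number the libraries as biological replicates. Their titles carry dates or the name of a set, some shared between strains: 1 L4 library of each of the 5 strains bears the same set name, N2 shares dates with BB19 at L4 and with RB886 and BB3 in embryos, and RB886 shares one with BB3 at L4. Within RB886, 2 of the 3 embryo libraries bear what reads as the same date, so they may not be separate cultures. What the dates stand for is not given in the sources used here, and group means left no way to use them as a block. The z-value behind the deposited p-values was 0.923 to 1.03 times, as a median per comparison, the one that counting error alone gives. Typically, those p-values therefore measure counting error and little of the spread between libraries. That median covers genes with means of at least 100 and leaves out the smallest log2 changes. Genes with such small changes can depart: adr-1 in BB3 embryos had a deposited adjusted p of 0.925 at means of 6290 in N2 and 6550 in BB3. The typical difference between the alleles of a gene, among genes with means of at least 100, limited the spread between mutant libraries. N2 libraries cancel in that difference, as does any spread that both strains share, so neither of these was limited. If libraries are independent, the typical spread between mutant libraries was at most 11.23% (adr-1) and 11.11% (adr-2) in embryos. At L4 it was at most 19.7% (adr-1) and 11.9% (adr-2). At the smaller of these per stage, and with libraries drawn independently, a simulated strain with no change had 3960 genes called in embryos and 4340 at L4, and 1635 and 1943 genes were called in both of 2 such strains. Genes called at least 2-fold in both were rare in the same simulation, at a mean of 1.73 and 3.11. At a spread of 20% the numbers in both were 3223 and 3615, and 7.56 and 10.7 at 2-fold. The genes changed at least 2-fold in both alleles are therefore given first in each comparison. Every simulated gene had the same spread, so the simulated counts do not cover genes that vary more between libraries. Genes named as the largest changes of a comparison are those among genes with a mean of at least 10, taken over the N2 and the mutant mean, and a finite ratio in the strains named.

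The targeted genes were lower in the strains that carry their mutations, with 1 departure at L4. In the authors' deposited table the log2 fold change of adr-1 (H15N14.1) in embryos was −2.05 in BB19 and −2.55 in BB2, from N2 means of 6290 and 6520 normalised counts. It was −0.06 in RB886 and 0.06 in BB3. The log2 fold change of adr-2 (T20H4.4) in embryos was −3.99 in RB886 and −4.11 in BB3, and −0.16 in BB19 and −0.22 in BB2. At L4 adr-2 stood at −3.61 in RB886 and −3.51 in BB3, and adr-1 at −1.69 in BB19. The libraries labelled BB2 kept more adr-1 RNA at L4, with a log2 fold change of −0.90, 0.537 of the N2 level against 0.309 in BB19. The same libraries had less adr-2 than N2, with a log2 fold change of −0.65 (adjusted p = 1.13e-29), whereas adr-2 in BB19 at L4 stood at 0.06 (adjusted p = 0.127 in the authors' deposited table). Every direction drawn from BB2 at L4 below is that of the libraries labelled BB2. The reads that remain over both genes in their own mutants can come from the parts outside each deletion, so they do not measure protein.

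**Figure D1:**
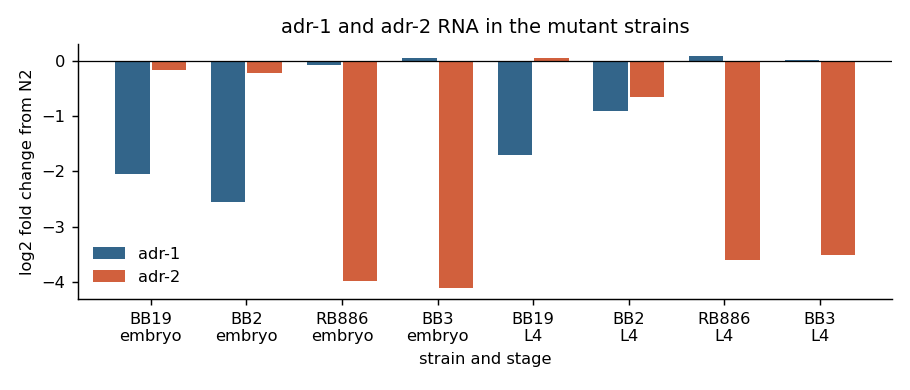
Log2 fold change of adr-1 and adr-2 RNA from N2 (vertical axis) in each mutant strain and stage (horizontal axis), from the authors' deposited table; each bar is 1 comparison of group means, without an error bar. adr-1 was lower in BB19 and BB2 and adr-2 in RB886 and BB3, and the libraries labelled BB2 at L4 had a smaller loss of adr-1 (−0.90) and a lower level of adr-2 (−0.65).

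Embryos without intact adr-1 had higher RNA of nerve, muscle and gut genes and lower RNA of oocyte and germline genes. A later average age of these embryos than of N2 was not excluded as a source of this pattern. The first comparison asked which embryonic RNAs change when the regulator of editing is disrupted, starting from its target adr-1, at −2.05 and −2.55. In both alleles 464 genes were at least 2-fold higher and 17 at least 2-fold lower. The largest rise was that of C08F11.1, from a mean of 0.489 in N2 to 68.5 in BB19, with log2 fold changes of 7.13 and 7.06 in BB19 and BB2. Among the 10 genes with the largest increase in both alleles were ZK1025.3 (2.47 and 3.25), Y69H2.14 (2.18 and 1.94) and its neighbour in name Y69H2.15 (1.89 and 1.95). The others were C30F2.3 (1.89 and 1.87), abu-1 (1.86 and 1.94), of a family induced when the unfolded protein response is blocked, Y73F4A.2 (1.89 and 1.81) and twk-33, a potassium channel subunit (1.77 and 1.99). ZK1025.2 and ZK1025.8 had identical values (1.77 and 2.75), so their reads are shared and neither can be named as the source.

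Ranked by the smaller change of the alleles, the strongest decrease in the adr-1 mutant embryos after adr-1 itself was that of D2005.1, a near neighbour of adr-1 on chromosome I in the WBcel235 annotation, at −1.56 and −1.51 in the authors' deposited table. B0511.11 followed at −1.87 and −1.35. Y46G5A.34 (−1.05 and −1.07), the acyltransferase-like gene oac-52 (−1.02 and −1.15), the predicted chemoreceptor sri-59 (−1.01 and −1.50) and Y37B11A.2 (−1.01 and −0.88) were also lower. So were 3 cuticle collagen genes, col-175 (−1.27 and −0.94), rol-8 (−0.87 in BB19) and sqt-1 (−1.35 and −0.87). At the deposited adjusted p alone, 8100 genes were called in BB19 (3566 higher, 4534 lower) and 9625 in BB2 (5080 higher, 4545 lower). Of these 2796 were higher and 2807 lower in both alleles, where independent lists would share 686 and 780, and 711 were called in opposite directions. Independent lists are not the value for no change, since the N2 libraries are shared: 2 unchanged simulated strains had 1635 genes called in both, and 3223 at a spread of 20%.

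Most neuronal genes were higher in the adr-1 mutant embryos. In BB19 and BB2, 62 and 64 of them were called higher (64 and 65 adjusted over the list alone), 55 of 79 in both alleles, with median log2 fold changes of 0.49 and 0.51. They included egl-21, a carboxypeptidase of neuropeptide processing (0.75 and 0.79), unc-13, which primes synaptic vesicles (0.50 and 0.41), unc-31, which acts in dense core vesicle release (0.58 in BB19), and unc-25, the glutamate decarboxylase of GABA neurons (0.84 in BB2). Muscle genes were called higher for 43 and 32 of 50 members (43 and 32 adjusted over the list alone), with none lower in BB19 and 13 lower in BB2. Those higher included the pharyngeal myosin gene myo-1, listed as let-75 (0.85 and 0.56), twitchin, unc-22 (0.72 and 0.47), and titin, ttn-1 (0.41 and 0.15). Of 40 intestinal genes 22 and 24 were higher (22 and 25 adjusted over the list alone), such as the aspartyl proteases asp-5 (0.84 and 0.71) and asp-6 (0.73 and 0.55). Antimicrobial genes were higher for 22 members in each strain (24 and 23 adjusted over the list alone), led by dod-19 (1.13 and 1.17) and the lysozyme lys-8 (0.63 and 0.68). Each of these 4 lists lay above random lists matched on expression in both alleles, with adjusted permutation p-values from 0.000313, reached at an unadjusted 0.0001, the smallest the random lists can give, to 0.0024. Called lower were 1 and 4 neuronal, 6 and 4 intestinal and 1 and 2 antimicrobial genes (1 and 5, 6 and 6, 1 and 2 adjusted over the list alone). Stress genes (medians 0.14 and 0.18; 32 members higher in each strain, 33 adjusted over the list alone) and cytosolic ribosomal protein genes (0.12 and 0.05; 57 and 35 higher, 60 and 38 adjusted over the list alone) also lay above random lists (adjusted permutation p = 0.000313 for each), with 7 and 15 stress and 6 and 11 ribosomal protein genes lower (8 and 16, 6 and 12 adjusted over the list alone).

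Cuticle collagens were higher for 71 of 178 members in BB19 and 68 of 179 in BB2 and lower for 30 and 22 (72, 69, 33 and 23 adjusted over the list alone), among the higher col-74 (0.79 and 0.90) and col-165 (0.70 and 0.69). Their median of 0.25 in BB19 passed the list test (adjusted permutation p = 0.000313) and that of 0.21 in BB2 did not (0.0778), and in BB19 their mean of 0.0791 lay below that of random lists. Genes of moulting and the apical matrix split, with 18 higher and 9 lower in BB19 (19 and 10 adjusted over the list alone) and 11 higher and 20 lower in BB2 (12 and 21 adjusted over the list alone). The moulting peroxidase mlt-7 was higher in both (1.03 and 0.97), and the list passed the test in BB19 only (adjusted permutation p = 0.000313, against 0.744 in BB2; the difference between the alleles was not tested).

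Oocyte and germline genes were lower in the adr-1 mutant embryos for 47 and 43 of 62 members (49 and 43 adjusted over the list alone), 39 of them in both alleles, with medians of −0.21 and −0.18. They included glh-4, a germline helicase (−0.94 and −0.81), the yolk receptor gene rme-2 (−0.67 in BB19), the eggshell gene cbd-1 (−0.35 and −0.37) and mex-1, a maternal RNA-binding protein (−0.60 in BB2). RNA interference and small RNA genes were lower for 31 and 32 of 51 members (32 and 33 adjusted over the list alone), such as the exonuclease xrn-2 (−0.53 and −0.84) and the Argonaute alg-2 (−0.41 in BB2). Both lists lay below random lists in both alleles (adjusted permutation p from 0.000313 to 0.0164). Early zygotic genes were lower for 28 and 18 of 51 members (28 and 18 adjusted over the list alone), with lin-26 at −0.10 and −0.19, and passed the list test in BB19 (adjusted permutation p = 0.0031) and not in BB2 (0.149). Histone genes were lower for 39 and 44 of 79 members and higher for 0 and 13 (41, 46, 0 and 13 adjusted over the list alone), but with medians of −0.08 and −0.10 the list did not pass the test (adjusted permutation p = 0.317 and 0.213). Vulval genes were lower for 23 and 33 of 60 members and higher for 7 and 9 (24, 33, 7 and 11 adjusted over the list alone) and did not pass the list test either (0.649 and 0.208). Vitellogenins, the yolk protein genes, were lower for 5 of 6 members in BB19 and 1 in BB2 (5 and 1 adjusted over the list alone), with vit-6 at −1.63 in BB19 from an N2 mean of 39.4, and passed the list test in BB19 (adjusted permutation p = 0.000576) and not in BB2 (0.107). Sperm genes had medians of −0.38 and −0.22 with 5 and 4 members called lower (0 and 2 adjusted over the list alone) and lay below random lists (adjusted permutation p = 0.000313 in both). Of the 9 transcripts with long-known editing sites 6 and 7 were lower (6 and 7 adjusted over the list alone), among them alh-7 (−0.58 and −0.73), whereas clec-41 was higher (1.00 and 0.95); the list passed in BB2 (adjusted permutation p = 0.0062) and not in BB19 (0.645). The intracellular pathogen response genes had 9 members higher in each strain (9 and 6 adjusted over the list alone), such as skr-3 (0.56 in BB2), and did not pass (0.0950 and 0.155).

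Embryos without editing showed fewer changes, with higher oocyte and germline RNA and lower ribosomal protein RNA. In the adr-2 mutants, with adr-2 at −3.99 and −4.11, 71 genes were at least 2-fold higher and 20 at least 2-fold lower in both alleles. The authors' deposited table put C08F11.1 first again, at 7.26 and 6.87, followed by sdz-20 (2.17 and 2.27). C23H5.4 (1.79 and 1.96), C23H5.6 (1.42 and 1.47) and C23H5.5 (1.33 and 1.40), which carry the same clone name, were all higher, as were F36F12.3 (1.47 in RB886), Y53G8AM.6 (1.41 and 1.41), the predicted chemoreceptor srh-198 (1.37 and 1.54), the transporter gene pgp-12 (1.37 and 1.56) and F33C8.4 (1.81 in BB3). The most abundant of the genes with a large decrease was nsy-1, a MAP kinase kinase kinase of the ASK1 family, from 3220 to 984 normalised counts in RB886 and from 3070 to 933 in BB3 (−1.71 and −1.72). Y102A5C.6 (−4.14 and −3.63), the chemoreceptor gene srw-85 (−5.89 and −3.37), the nuclear receptor gene nhr-82 (−1.82 and −2.29), the globin gene glb-16 (−2.31 and −1.31) and lact-6 (−2.28 and −1.17) fell from N2 means of 16.8 to 51.7. Y17D7C.4 (−1.20 and −1.24), B0511.11 (−1.18 and −1.20) and Y22D7AL.11 (−1.26 and −1.12) were lower too. At the deposited adjusted p, 4922 genes were called in RB886 (2506 higher, 2416 lower) and 4411 in BB3 (2827 higher, 1584 lower). Both alleles shared 1208 higher and 801 lower genes, against 268 and 145 for independent lists, and 393 were called in opposite directions. Together these shared calls exceed the 1635 of simulated unchanged strains and fall short of the 3223 at a spread of 20%.

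Oocyte and germline genes were called higher for 50 and 35 of 62 members in RB886 and BB3 embryos (55 and 41 adjusted over the list alone), 30 in both, with medians of 0.25 and 0.12. Examples were lin-41, a regulator of oocyte maturation and larval timing (0.51 and 0.41), and mex-1 (0.33 and 0.19). Neuronal genes were higher for 29 and 37 of 79 members and lower for 10 and 2 (34, 44, 13 and 2 adjusted over the list alone), 24 higher in both, including egl-21 (0.32 and 0.43). Histone genes were higher for 35 and 54 of 79 members and lower for 18 and 3 (39, 61, 19 and 3 adjusted over the list alone), 28 higher in both and 16 in opposite directions in the alleles. Those higher included his-47 (0.20 and 0.28) and his-66 (0.31 and 0.31), copies of which share most of their reads. Cytosolic ribosomal protein genes were lower for 67 and 55 members (70 and 61 adjusted over the list alone), 52 of 79 in both, with medians of −0.20 and −0.06. Sperm genes lay below random lists, with medians of −0.23 and −0.29, although 1 member was called lower in RB886 and 0 in BB3 (0 and 0 adjusted over the list alone). These 5 lists passed the list test in both alleles (adjusted permutation p = 0.000313 for each). Muscle and intestinal genes moved apart in the alleles. In RB886 24 of 50 muscle genes were lower and 9 higher (28 and 10 adjusted over the list alone), and in BB3 33 were higher and 2 lower (35 and 3 adjusted over the list alone). The split of the 40 intestinal genes was smaller, with 13 lower and 7 higher in RB886 (15 and 9 adjusted over the list alone) and 16 higher and 7 lower in BB3 (16 and 7 adjusted over the list alone). Both lists passed in each strain (adjusted permutation p from 0.000313 to 0.0427), with ttn-1 at −0.11 in RB886. RNA interference genes passed the list test in RB886, with 19 higher and 4 lower (21 and 4 adjusted over the list alone; adjusted permutation p = 0.000313), and not in BB3, with 16 higher and 4 lower (18 and 4 adjusted over the list alone; 0.109). So did antimicrobial genes, below random lists (adjusted permutation p = 0.0123 in RB886 and 0.445 in BB3). Collagens (median 0.15, adjusted permutation p = 0.000576) and vitellogenins (−0.50, 0.0037) passed in BB3 and not in RB886 (0.774 and 0.0506). The edited transcript rncs-1, a noncoding RNA with a long double-stranded stem, was lower in both alleles (−1.13 and −0.74).

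Changes shared by adr-1 and adr-2 mutant embryos were mostly increases. Called in both alleles of both genes were 662 genes higher and 277 lower, against 130 and 86.5 for independent lists. In a simulation of 4 unchanged strains that share the N2 libraries, added after the data were seen, 297 were higher and 306 lower in all 4, and 662 and 695 at a spread of 20%. The shared decreases therefore do not exceed that value at either spread, nor the shared increases at the larger. At least 2-fold in all 4 strains were 34 genes higher and 2 lower, the latter B0511.11 and B0507.7, where the simulation gave a mean of 0.51 and 0.15 even at a spread of 20%. Of the 34, 26 had an N2 mean under 10, and a larger spread of such genes was not simulated. The shared increases included the C-type lectin gene clec-76 (1.89 to 3.12), fipr-9 (2.47 to 3.63), abu-1 (1.67 to 1.94) and the hedgehog-related gene grd-6 (1.16 to 1.33). All 4 comparisons used the same N2 libraries, so chance low values of N2 add to the shared increases. Across 23569 to 23735 genes, the Pearson correlation of log2 fold changes was 0.564 between the adr-1 alleles, 0.480 between the adr-2 alleles, 0.524 between BB19 and BB3, 0.421 between BB19 and RB886, 0.494 between BB2 and BB3 and 0.391 between BB2 and RB886. Unchanged strains simulated against shared N2 libraries gave 0.467, and the covariances were 0.285, 0.191, 0.232, 0.179, 0.233 and 0.176 in the same order beside a simulated 0.132. Among genes with means of at least 100 the correlations were 0.561, 0.486, 0.504, 0.0825, 0.461 and 0.0633 beside a simulated 0.429. Their covariances were 0.0499, 0.0145, 0.0239, 0.0036, 0.0269 and 0.0035 beside 0.0078, or 0.0223 at a spread of 20%. The genes are not independent replicates.

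The authors also listed genes of each class, chosen on these samples, so their direction in the strains they were chosen on is not independent evidence. Of the 374 genes on the list of adr-1 increases in embryos, 154 were called higher in RB886 and 261 in BB3 (176 and 302 adjusted over the list alone), with medians of 0.53 and 0.82. Of the 46 adr-2 increases, 31 were higher in BB19 and 35 in BB2 embryos (35 and 36 adjusted over the list alone), with medians of 1.33 and 1.38. These 4 comparisons passed the list test (adjusted permutation p = 0.000229 for each), and all share the N2 libraries on which the lists were drawn up. The 7 adr-1 decreases did not pass in the adr-2 mutant embryos (adjusted permutation p = 0.433 in RB886 and 0.20 in BB3), and the 17 adr-2 decreases did not pass in the adr-1 mutant embryos (0.984 and 0.0695).

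At L4 the adr-1 mutants had higher RNA of moulting and apical matrix genes and lower RNA of sperm genes, and the alleles moved apart in yolk protein and oocyte genes. The target adr-1 stood at −1.69 in BB19 and −0.90 in the libraries labelled BB2. In both, 306 genes were at least 2-fold higher and 228 at least 2-fold lower. The largest increases common to both were those of F25D1.3 (3.17 and 3.05 in the authors' deposited table), hsd-3, a hydroxysteroid dehydrogenase-like gene (3.15 and 2.75), and mab-3, a DM-domain transcription factor that represses yolk genes in males (2.66 and 2.71). Let-653, which encodes an apical matrix protein of tubes and cuticle, rose from 131 to 648 normalised counts in BB19 and from 118 to 537 in the libraries labelled BB2 (2.19 on the log2 scale). B0205.4 (2.58 and 2.53), the glucuronosyltransferase-like genes ugt-57 (2.20 and 2.18) and ugt-40 (2.09 in the libraries labelled BB2), the patched-related ptr-10 (2.16 in BB19), T23F6.5 (2.22 and 2.12) and the collagen gene col-176 (2.17 and 2.12) were higher as well. Among genes with such a mean of at least 10, the strongest decreases were those of abu-4 (−2.97 and −3.15), the C-type lectin gene clec-197 (−3.47 and −2.80), F59B2.12 (−4.63 and −2.77), Y5H2A.4 (−2.67 and −2.84) and the astacin protease genes nas-1 (−2.44 and −2.83) and nas-30 (−3.23 and −2.28). ZC21.9 (−2.23 and −2.43), R03C1.1 (−2.17 and −2.66), the glutamine-rich pqn-57 (−2.13 and −4.06) and AC3.16 (−2.12 and −2.46) were lower too. By the deposited adjusted p, 8246 genes were called in BB19 (4420 higher, 3826 lower) and 8785 in the libraries labelled BB2 (4123 higher, 4662 lower). They shared 1932 higher and 2196 lower genes, against 737 and 722 for independent lists, and 1339 genes were called in opposite directions. Simulated unchanged strains shared 1943, and 3615 at a spread of 20%. In BB19 alone, without the libraries labelled BB2, 765 genes were at least 2-fold higher and 502 lower.

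Moulting and apical matrix genes were higher at L4 for 23 of 47 members in BB19 and 29 in the libraries labelled BB2, and lower for 13 and 6 (23, 29, 13 and 6 adjusted over the list alone), with medians of 0.13 and 0.55. Those higher included the moulting protease inhibitor mlt-11 (1.02 and 1.32), the fibrillin-like fbn-1 (1.79 and 2.07) and noah-1, an apical matrix protein (1.09 and 1.36). Sperm genes were lower for 58 and 64 of 72 members (61 and 64 adjusted over the list alone), 54 in both, such as spe-11, a sperm-supplied factor of embryogenesis (−0.48 and −0.35), and msp-113, a major sperm protein gene (−0.21 and −0.39). The sperm membrane fusion gene fer-1 was lower in BB19 (−0.29) and stood at 0.04 in the libraries labelled BB2. The msp genes are near-identical copies whose reads can be divided among them. Ribosomal protein genes were higher for 71 and 76 of 79 members (73 and 77 adjusted over the list alone), with medians of 0.14 and 0.27. Cuticle collagens went both ways, with 98 lower and 39 higher in BB19 (101 and 39 adjusted over the list alone) and 74 lower and 51 higher in the libraries labelled BB2 (75 and 53 adjusted over the list alone). Col-12 (−1.06) and col-120 (−1.61) fell in BB19, dpy-10 rose in BB19 (1.51), as did dpy-7 (1.03), and dpy-5 was lower in the first (−0.73) and higher in the second (0.39). These 4 lists passed the list test in both strains (adjusted permutation p from 0.000313 to 0.0025).

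All 6 vitellogenin genes were higher in BB19 and lower in the libraries labelled BB2 at L4 (6 and 6 adjusted over the list alone), with medians of 0.43 and −1.78. Vit-4 was at 0.46 and −1.84. Oocyte and germline genes did likewise, higher for 41 of 62 members in BB19 and lower for 48 in the libraries labelled BB2 (43 and 50 adjusted over the list alone), 38 of them in opposite directions, such as mex-1 (0.37 and −1.12). Both lists passed the list test in each strain (adjusted permutation p from 0.000313 to 0.0017), on opposite sides. Histone genes were higher for 55 of 79 members in BB19 and 24 in the libraries labelled BB2, where 23 were lower (56, 29 and 23 adjusted over the list alone), and passed in both (0.000313 and 0.0131). Muscle genes were below random lists in BB19 (20 lower, 11 higher, the same counts adjusted over the list alone) and above them in the libraries labelled BB2 (43 higher, 43 adjusted over the list alone), with adjusted permutation p of 0.0444 and 0.0062. Vulval genes passed in BB19 (29 of 60 higher, 29 adjusted over the list alone; 0.0053), with cdh-3, a cadherin gene, at 1.07. In the libraries labelled BB2 alone, antimicrobial, neuronal, intestinal and stress genes lay above random lists, with 26, 19, 27 and 37 members higher (27, 19, 27 and 37 adjusted over the list alone), and RNA interference genes below them (17 lower, 19 adjusted over the list alone). Called the other way there were 9, 13, 5 and 8 members of the first 4 and 8 of the last (10, 13, 5, 8 and 8 adjusted over the list alone). Tbh-1, the octopamine synthesis enzyme, was at −3.05 and lys-1 at 0.30 there, and the ciliary dynein gene che-3 was lower in both strains (−1.15 and −0.43). The differences between the strains were not tested.

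At L4 the adr-2 mutants had lower yolk protein RNA and higher moulting gene RNA in both alleles. With adr-2 at −3.61 in RB886 and −3.51 in BB3, 117 genes were at least 2-fold higher and 65 at least 2-fold lower in both. T05A7.11 led the increases, from 6.49 to 207 normalised counts in RB886 and from 6.58 to 210 in BB3 (4.99 on the log2 scale), according to the authors' deposited table. F57A10.2 (2.99 and 3.03), F53A2.3 (2.82 and 2.98), mab-3 (2.43 in RB886), clx-1, a collagen-like gene (2.44 and 2.37), and C23H5.4 (2.00 and 2.04) followed. B0310.10, B0310.12 and F52F10.7 had the same values in both alleles (1.91 and 1.90), and K03B8.21 (2.11 and 1.89) had a copy with identical values, so the source of these reads is uncertain. Among genes with such a mean of at least 10 and a finite ratio, the deepest decreases were those of Y102A5C.5 (−7.18 and −6.16) and Y102A5C.6 (−5.17 and −4.15), and of the C-type lectin gene clec-174 (−3.81 and −3.69). Haf-6, an ABC transporter gene that acts in RNA interference, fell from 638 to 149 normalised counts in BB3 (−2.10), and was also called lower in RB886. F59A7.2 (−2.22 and −2.46), the lipase-like lips-6 (−1.89 and −2.02), F59B2.12 (−1.77 and −1.71), F26D2.16 (−2.22 and −1.70) and glb-16 (−1.69 and −2.18) were lower too. By the deposited adjusted p, 4520 genes were called in RB886 (2435 higher, 2085 lower) and 4325 in BB3 (2177 higher, 2148 lower). The alleles shared 1004 higher and 688 lower genes, against 213 and 180 for independent lists, and 591 were called in opposite directions. Together the shared calls in 1 direction are fewer than the 1943 of simulated unchanged strains at a spread of 11.9%, so their number alone does not exclude chance values of N2.

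All 6 vitellogenin genes were lower in both adr-2 mutants at L4 (6 and 6 adjusted over the list alone), with medians of −0.81 in RB886 and −0.19 in BB3, and vit-6 at −0.72 and −0.20. Moulting genes were higher for 28 and 21 of 47 members and lower for 2 and 10 (30, 22, 3 and 11 adjusted over the list alone), 20 higher in both, including mlt-11 (0.89 and 0.67) and noah-1 (0.79 and 0.65). The moulting list lay above random lists in all 4 mutant strains at L4, each compared with the same N2 libraries. A different average age within L4 was not tested for the moulting list. For the vitellogenins such an age difference cannot be told apart from the strains' own effects. Cuticle collagens were divided, with 55 higher in each strain and 57 and 70 lower (59, 58, 63 and 77 adjusted over the list alone). Col-129 (−1.06 in RB886) and col-88 (−0.70 in BB3) were among the lower ones. These 3 lists passed the list test in both alleles (adjusted permutation p from 0.000313 to 0.0015), although in BB3 the mean of the collagens, 0.108, lay on the other side of random lists from their median of −0.07. Intracellular pathogen response genes were higher for 7 and 10 members and lower for 3 and 1 (7, 10, 3 and 1 adjusted over the list alone), such as W08A12.4, which current annotation places in the pals family (1.53 and 1.76), and dct-3 (0.72 and 0.59), with adjusted permutation p of 0.0360 and 0.000313. Histone, ribosomal protein and muscle genes passed in RB886, with 41, 47 and 28 members higher (44, 50 and 30 adjusted over the list alone), and not in BB3 (adjusted permutation p = 0.211, 0.869 and 0.157). Oocyte genes passed in RB886, below random lists at a median of −0.04, although 4 were called higher and 4 lower (4 and 2 adjusted over the list alone). In BB3 29 were lower and 5 higher (31 and 6 adjusted over the list alone) and the list did not pass (0.0762). Sperm genes passed in BB3, at a median of −0.05 with 3 members lower and 1 higher (2 and 0 adjusted over the list alone), and not in RB886 (adjusted permutation p = 0.557). The noncoding rncs-1 was lower in both alleles (−1.47 and −0.88), and also in the libraries labelled BB2 (−0.99).

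**Figure D2:**
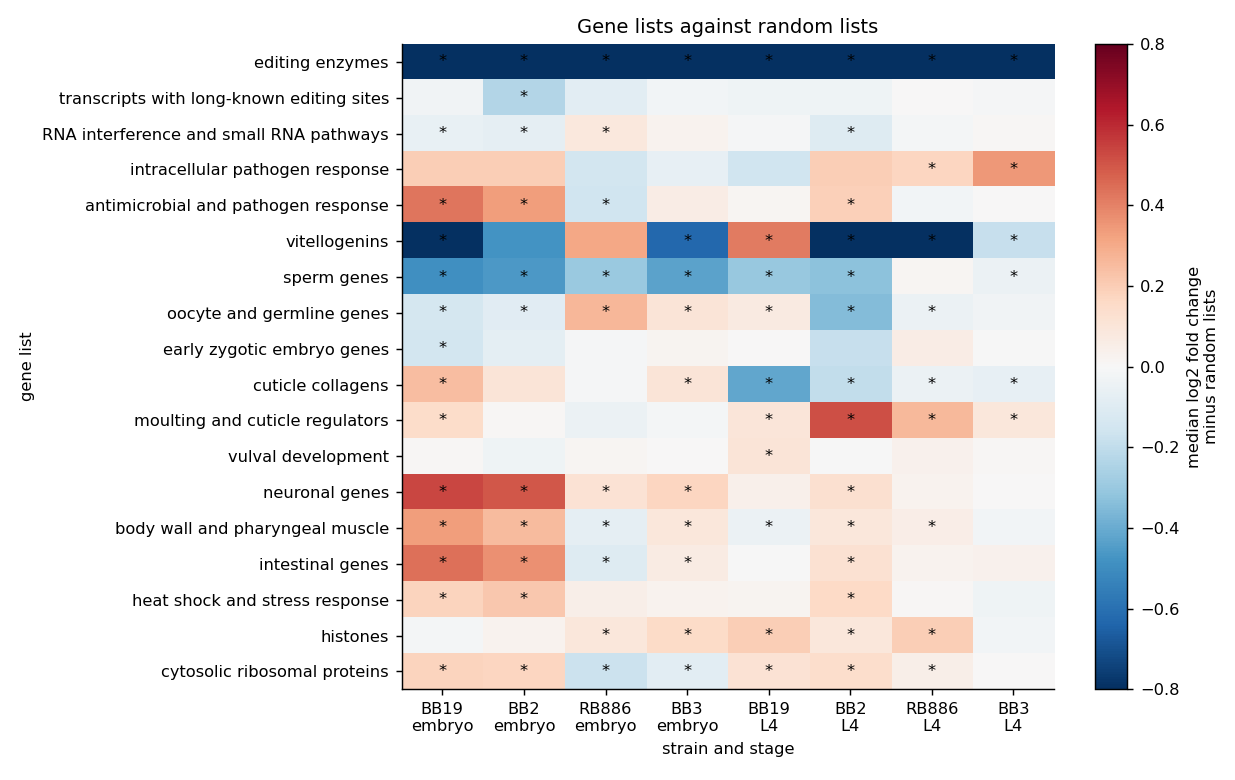
Median log2 fold change of each gene list (vertical axis) minus that of expression-matched random lists, by strain and stage (horizontal axis), as a colour from blue (lower) to red (higher); colours end at 0.8 in either direction. An asterisk marks an adjusted permutation p under 0.05, reached by 84 of 144 tests. The editing enzyme list passed in every strain and stage, which follows from its holding the mutated genes themselves. In adr-1 mutant embryos neuronal genes had medians of 0.49 and 0.51, and at L4 vitellogenins were at 0.43 in BB19 and −1.78 in the libraries labelled BB2.

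At L4 the changes common to both genes were again mostly increases. Called in both alleles of adr-1 and of adr-2 were 645 genes higher and 344 lower, against 79.6 and 62.0 for independent lists, all against the same N2 libraries. Simulated unchanged strains gave 396 and 408 in all 4, and 824 and 843 at a spread of 20%, so only the increases exceed a simulated value, and only at the smaller spread. With BB19 alone for adr-1 the observed numbers were 707 and 448. At least 2-fold in all 4 strains were 84 genes higher and 28 lower, 5 of the latter listed at 0 in at least 1 mutant strain, against a simulated 1.1 and 0.22 at a spread of 20%. The increases included mab-3 (up to 2.71), let-653 (at least 1.22), dpy-10 (up to 1.83), the cadherin gene cdh-7 (1.11 to 2.07) and the lipocalin-related lpr-4 (1.08 to 1.75). Many of the 84 had values identical or nearly identical to those of others, as copies sharing reads would, and such reads cannot be assigned. Simulated genes were drawn independently, so the 84 may hold far fewer separate changes than that comparison assumes. The decreases included clec-161 (−5.61 to −1.13), nas-17 (−1.47 in BB3), scl-7 (−3.94 to −2.17) and abu-9 (−4.06 to −1.27). The Pearson correlation across 21706 to 22057 genes was 0.467 between the adr-1 alleles, 0.472 between the adr-2 alleles, 0.573 between BB19 and BB3, 0.386 between BB19 and RB886, 0.455 between the libraries labelled BB2 and BB3 and 0.519 between the libraries labelled BB2 and RB886, beside a simulated 0.494. The covariances in that order were 0.244, 0.171, 0.237, 0.166, 0.20 and 0.234 beside 0.118. Among genes with means of at least 100 the correlations were 0.553, 0.374, 0.654, 0.322, 0.504 and 0.634 beside a simulated 0.501. Their covariances were 0.0745, 0.0200, 0.0526, 0.0248, 0.0436 and 0.0537 beside 0.0121, or 0.0301 at a spread of 20%. The highest correlations, of BB19 with BB3 and of the libraries labelled BB2 with RB886, joined strains mutated in different genes. By that measure agreement at L4 did not follow the mutated gene, although the largest covariance was that of the adr-1 alleles. Of the authors' 265 adr-1 increases at L4, 177 were higher in RB886 and 231 in BB3 (192 and 237 adjusted over the list alone; medians 0.83 and 0.97), and of their 187 decreases 111 were lower in RB886 and 154 in BB3 (1.2e2 and 166 adjusted over the list alone), with medians of −0.53 and −0.79. Of their 100 adr-2 increases, 83 were higher in BB19 and 92 in the libraries labelled BB2 (84 and 93 adjusted over the list alone; medians 1.38 and 1.95), and of the 44 decreases 27 and 25 were lower and 9 and 7 higher (28, 26, 10 and 7 adjusted over the list alone). Each passed the list test (adjusted permutation p = 0.000229), on lists chosen from these samples.

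The largest changes of single strains were in part shared with other strains. In the authors' deposited table, those called at 2-fold in 1 strain alone at that stage included the Wnt gene lin-44 in BB19, at −2.79 in embryos and −3.27 at L4 (0.30 and 0.29 in BB2). H19N07.3 (−2.60) and col-106 (−2.39) in BB19 embryos, nhr-155 (5.35) and C50F7.9 (−4.23) in BB19 at L4 and T08G3.4 (2.26) in RB886 embryos were others. F56A4.9 was higher in BB2 at both stages (6.06 and 4.94), and clec-209 (5.41) and Y116A8A.7 (−2.56) changed in BB2 embryos and Y19D10A.7 (5.24) in the libraries labelled BB2 at L4. Other genes named by the same rule were called at 2-fold elsewhere too. In embryos srw-85 was lower in BB2 (−5.39), RB886 (−5.89) and BB3 (−3.37), numr-1 was higher in BB19 (2.33) and BB2 (1.25), and Y50E8A.19 was higher in BB3 (2.13), BB2 (1.46) and RB886 (1.46). At L4 F26D2.16 was lower in BB19 (−5.52), the libraries labelled BB2 (−1.89), RB886 (−2.22) and BB3 (−1.70). The gene cpr-2 was higher in BB19 (2.39), the libraries labelled BB2 (3.85) and RB886 (2.55), and fkh-3 (3.98 and 2.51) and K03A11.1 (3.94 and 2.67) in BB19 and BB3. The libraries labelled BB2 and RB886 had lower ZK813.3 (−7.56 and −1.82), ZK813.2 (−6.56 and −2.90), Y62H9A.3 (−5.43 and −1.88) and scl-22 (−3.38 and −3.98) at L4, each of which was called higher in BB19.

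Most genes called in a strain at one stage were not called the same way at the other. In BB19, 745 genes were higher and 623 lower at both stages, against 638 and 693 for independent lists. In BB2 and the L4 libraries labelled BB2 the counts were 1199 and 1131, against 850 and 847. RB886 had 463 and 322, against 245 and 201, and BB3 had 430 and 253, against 248 and 137. The Pearson correlation of embryo with L4 log2 fold changes lay between −0.0367 in BB19 and 0.0203 in BB3 across 21097 to 21360 genes. Among genes with means of at least 100 it was −0.20 in BB19, −0.0274 in BB2, −0.0522 in RB886 and −0.0632 in BB3. In both adr-1 alleles at both stages 381 genes were higher and 90 lower, against 227 and 252 for independent lists, and in both adr-2 alleles 77 and 76, against 50.7 and 22.8. C08F11.1, at 6.87 to 7.26 in the embryos of all 4 strains, ranged from −0.55 to 0.38 at L4, where its N2 mean was 34.8 against 0.489 in embryos. Of the genes at least 2-fold changed in both adr-2 alleles at both stages, 12 were found, among them adr-2, haf-6, glb-16, Y102A5C.5, Y102A5C.6, C23H5.4 and C23H5.6, and 2 listed at 0 in the mutants, Y102A5C.36 and Y73B3A.t1.

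Tagged ADR-1 pulled down more muscle and long-known edited transcripts in young adults than expression-matched random lists hold. The authors' lists, which hold only enriched genes, named 1237 genes in HH76, with adr-2 present, and 1215 in HH134, without it. They shared 828 genes, and 409 and 387 were on 1 list alone. Left out of the ranking that follows were 164 genes of HH76 and 140 of HH134 treated as having no finite fold. Among the rest, by the authors' deposited table, the strongest enrichment in both was that of F31F4.1, with log2 values of 9.35 and 8.37. The list of the 10 strongest went on with gid-7 (8.58 and 7.90), the epidermal transcription factor gene grh-1 (8.24 and 7.43), Y41D4A.7 (7.17 and 7.36), fipr-29 (7.08 and 6.86), Y71H2B.8 (6.75 and 7.23), sbsp-1 (6.53 and 6.80), Y65B4A.11 (7.09 in HH134), sydn-1, which acts in neurons (6.96 and 6.47), and the kinase-like scyl-1 (6.93 and 6.02). Bound on either list were 26 of 50 muscle genes, 7 of 9 transcripts with long-known editing sites and 7 of 39 intracellular pathogen response genes, where lists matched on embryo and L4 means held a median of 8, 1 and 1 (adjusted permutation p = 0.0009, 0.0009 and 0.0050). Of the 79 histone and 79 ribosomal protein genes 0 were bound, against 11 and 12 in matched lists (adjusted permutation p = 0.0050 for each). Both editing enzyme genes, 18 of 179 collagens, 10 of 47 moulting genes and 9 of 79 neuronal genes were bound and did not pass (adjusted permutation p = 0.0642, 0.903, 0.117 and 0.495), and neither did vitellogenins and sperm genes, with 0 bound (0.852 and 0.121). This test was chosen after the data were seen. HH76 and HH134 both express tagged adr-1, so its own transcript is not an independent target. How inputs were used is not given, so differences in RNA level between the tagged strains and BB21 may enter the enrichment.

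Bound genes were found among the increases more often than expression-matched genes in 6 of the 8 comparisons with N2. In BB19 embryos 523 bound genes were higher, against 208 over all genes tested and 288 in expression-matched random lists. In BB3 embryos the number was 344 (262 matched), in BB2 embryos 487 (371 matched) and in BB3 at L4 299 (216 matched), each with an adjusted permutation p of 0.000229. RB886 and the libraries labelled BB2 at L4 had 308 and 502 (267 and 446 matched; adjusted permutation p = 0.0082 and 0.0016). RB886 embryos (252, 229 matched) and BB19 at L4 (417, 430 matched) did not pass. Among the decreases the direction depended on the background. In BB19 embryos 319 bound genes were lower, more than the 265 over all genes tested and fewer than the 496 in matched lists. The libraries labelled BB2 at L4 had 301 (290 over all genes, 402 matched) and BB3 at L4 had 159 (133 over all genes, 220 matched). In RB886 embryos 331 bound genes were lower, more than over all genes tested (141) and in matched lists (290; adjusted permutation p = 0.0071). Bound genes are more highly expressed than most, and such genes are called more often.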

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

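All tests in this part, of the difference between stages, were chosen after the data were seen. For each list and each mutated gene, the log2 changes of the alleles were averaged, and the median of L4 minus embryo over the members was compared with expression-matched random lists. Of 36 such tests, 20 passed after adjustment, and their difference between stages is what singled them out. Their adjusted permutation p-values lay between 0.000277, which stands for the smallest that the random lists can give, and 0.0425. At L4 the adr-1 average includes the libraries labelled BB2.

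For adr-1 mutants, cuticle collagens had the largest median difference (−0.63), with list medians of 0.18 in embryos and −0.34 at L4. Neuronal genes (−0.47), antimicrobial genes (−0.44), intestinal genes (−0.24), vitellogenins (−0.22) and muscle genes (−0.13) also lay lower at L4 than in embryos, while moulting genes (0.27) and histones (0.25) lay higher. For adr-2 mutants, vitellogenins (−0.50), oocyte and germline genes (−0.23), collagens (−0.21), neuronal genes (−0.17), stress genes (−0.0835) and RNA interference genes (−0.0454) lay lower at L4. Moulting genes (0.25), sperm genes (0.22), intracellular pathogen response genes (0.20), ribosomal protein genes (0.18), early zygotic genes (0.0953) and intestinal genes (0.0662) lay higher. In 5 of these differences the medians of the alleles went opposite ways from embryo to L4, so the average stands for neither. Vitellogenins went from −0.84 to 0.43 in BB19 and from −0.15 to −1.78 in BB2, and from 0.37 to −0.81 in RB886 and −0.50 to −0.19 in BB3. Muscle genes went from 0.27 to −0.02 in BB19 and from 0.13 to 0.20 in BB2. Intestinal genes (−0.10 to 0.05 in RB886, 0.08 to 0.03 in BB3) and early zygotic genes (−0.01 to 0.06 in RB886, 0.04 to 0.00 in BB3) also diverged. Single alleles were not tested for a difference between stages. These differences are given without subtracting random lists. In adr-1 mutants random lists had medians of 0.11 beside moulting genes, 0.12 beside histones, 0.14 beside muscle genes and 0.10 beside intestinal genes. They had 0.13 beside vitellogenins, 0.08 beside collagens, 0.01 beside neuronal genes and −0.09 beside antimicrobial genes. No explanation was tested for these differences.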

How the results depend on the processing

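Of the alternatives below, an assumed spread of 20% between libraries, all transcripts, copies counted once, expression-matched lists for bound genes and BB19 alone for adr-1 were chosen after the data were seen. No paired analysis was possible because only group means are given, and for the same reason leaving out libraries, other tools, other size factors, replicate blocks and other splits of the samples were not run. A fold limit of 2 lowers every count by its construction: embryo counts became 840 (BB19), 1598 (BB2), 261 (RB886) and 426 (BB3), and L4 counts 1267, 1342, 545 and 581 in that order of strains. Genes changed in both alleles became 481 (adr-1) and 91 (adr-2) in embryos and 534 and 1.8e2 at L4 (for adr-2, 117 higher and 65 lower), and their overlap 36 in embryos and 1.1e2 at L4 (84 higher and 28 lower). With a spread of 20% added to counting error, which also removes calls by its construction, the strains gave 689, 1983, 52 and 142 in embryos and 1280, 1330, 423 and 404 at L4. Both alleles then shared 518 and 26 genes in embryos and 582 and 144 at L4, with overlaps of 6 and 94.

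With an adjusted p under 0.01, the embryo overlap of both genes fell to 617, the stage overlaps to 897 (BB19), 5.1e2 (RB886, 312 higher and 196 lower) and 375 (BB3), and the bound genes to 519; the other 14 counts stayed within 1.5 times. A 4-fold limit left 456 bound genes. With BB19 alone, the adr-1 count at L4 was 8246, since a single strain has to pass. Filters on low means, no filter, all transcripts, recentred fold changes and copies counted once kept each count they were run on within 1.5 times. Recentring moved the share of higher calls most in BB19 embryos, from 44.02% to 47.49%.

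Of 144 list tests 84 passed, and 86, 72 and 63 did so with a minimum mean of 10, means in place of medians and unmatched lists. The 84 include every test of the editing enzymes, a list that holds the mutated genes themselves. The mean turned collagens to the other side of random lists in BB19 embryos (0.0791) and BB3 at L4 (0.108), while the median did not; the cause was not tested. Bound genes among the decreases turned from above to below the number expected once expression was considered in 5 of the 8 comparisons, past the threshold in 3 of them. In BB3 embryos (170, with 174 in matched lists) and BB19 at L4 (343, with 349) they did not differ past it. For the 3, odds ratios were taken on a background with a mean of at least 10. They were 0.691 in BB19 embryos, 0.645 in the libraries labelled BB2 at L4 and 0.820 in BB3 at L4. Against matched lists the ratio of observed to expected, a different measure, was 0.643, 0.749 and 0.723 in the same order. Of 16 tests of bound genes 15 passed, and 10 against matched lists. The deposited p-values mostly reflect counting error, so depth makes small changes of abundant genes pass.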

Other observations

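Apart from the tests of the authors' lists, the tests in this part, and the limits that decide them, were chosen and revised after the values were seen: genes listed at 0 were first left out of the neighbour test and of the genes changed in all 4 strains, the marker test first counted adr-2 itself among 6 markers, the test of N2 RNA first used a limit of 20% on srw-85, the tests of adr-2 first used counting error alone, the test of age within L4 first counted the adr-1 strains, and a cause peculiar to the gv6 allele was first left undecided.

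The genes on the authors' list of adr-1 decreases at L4 were higher in embryos of all 4 strains, with medians of 0.58 in BB19, 0.63 in BB2, 0.33 in RB886 and 0.38 in BB3, beside 0.05 to 0.20 in expression-matched random lists (adjusted permutation p = 0.000229 for each). In that order of strains 84, 85, 58 and 72 of these genes were called higher and 5, 6, 5 and 5 lower. The genes of the authors' adr-2 decreases in embryos lay lower at L4 in the adr-2 mutants (−0.72 in RB886 and −0.82 in BB3). Of 12 genes changed at least 2-fold in both adr-2 alleles at both stages, 5 of the 11 that could be placed lay within 3 genes of another, where random sets of genes gave a mean of 0.0282 (permutation p = 0.0001, the smallest it can give). These are the neighbours C23H5.4 and C23H5.6, and Y102A5C.5, Y102A5C.6 and Y102A5C.36. The first pair lies on chromosome IV and the other genes on chromosome V, while adr-2 lies on chromosome III. Whether the strains share differences other than their adr-2 alleles was not tested.

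The libraries labelled BB2 at L4 kept more adr-1 RNA than BB19 and had less adr-2 RNA than N2. RNA of N2 in these libraries cannot lower adr-2, which stood at −0.65 with a standard error of 0.235. That standard error allows for a spread between libraries of 19.7%, the larger value of adr-1 and adr-2 at L4. Whether loss of adr-1 as such lowers adr-2 at L4 stays open. In BB19 adr-2 stood at 0.0555 (standard error 0.234 at the same spread), less than 2 standard errors above the midpoint of 0 and −0.65. The standard error at the smaller spread of 11.9%, used in the simulations, would be lower and was not computed, so this result may depend on that choice. In embryos adr-2 was called lower in both adr-1 alleles (−0.16 and −0.22). RNA of an adr-2 mutant strain in these libraries stays open too: 5 other genes that mark both adr-2 strains all lay toward them, at a median share of 34.4% (7.35% to 56.6%), against 0.861% in BB2 embryos, where 3 of the 5 lay toward them (−9.20% to 25.9%), and the adr-1 level needs 30.98%. This is a hypothesis found and tested on the same data, and group means cannot tell which libraries it would concern. An effect peculiar to the gv6 allele or its background was not tested.

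Neuronal genes were higher in the embryos of all 4 mutant strains. In adr-2 mutants a later average age of the embryos, which could raise them, goes against oocyte and germline genes, which were higher by 0.18. In adr-1 mutants these genes were lower (−0.20). Early zygotic genes also lay below random lists, past the threshold in BB19 (adjusted permutation p = 0.0031) and not in BB2 (0.149). A later age may therefore account for the pattern there, in part or in whole, and its share was not estimated. An effect of the adr-1 genotype itself on these genes stays open beside a later age and was not tested.

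Vitellogenins and oocyte genes moved in opposite directions in the adr-1 alleles at L4, higher in BB19 and lower in the libraries labelled BB2. A different average age within L4 cannot be told apart from the strains' own effects here. The test used the adr-2 strains alone, since the adr-1 strains show the pattern itself. It asked only whether the lists move together, which age and a strain's own effect can both give, so it cannot separate them. In 2 of 2 adr-2 strains both lists lay below random lists, but they share the N2 libraries, and oocyte genes in BB3 did not pass (adjusted permutation p = 0.0762). RNA of an adr-2 strain in the libraries labelled BB2 stays open as well.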
